A study of Brassica napus with 6 samples.

How the data were processed

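Polyadenylated RNA from rapeseed (Brassica napus) shoot apices was sequenced in 6 libraries, 3 from the wild-type cultivar Westar and 3 from plants in which intron 2 of the BnaC3 copy of LEAFY had been deleted. Groups and replicate numbers were taken from the sample titles. The titles number the replicates but do not say whether they came from separate plants or pools, so the p-values measure the spread between these libraries, which may be partly technical.

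The authors deposited 1 table of raw read counts per gene, with 1 column per library and no pooling. Per the submitters' processing notes, HISAT2 2.2.1 and featureCounts were used, with no version for the counter. The genome build, the annotation, the strand setting and the treatment of multi-mapping reads are not given in the sources used here. Whether reads of near-identical homoeologous copies were split, shared or dropped is therefore unknown, and this can move counts between copies.

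The table held 100194 rows, of which 32414 had a count of 0 in every library. Each ID names a chromosome of the A or C subgenome, or an unplaced scaffold (6103 rows), followed by a running number. This number was read as the order along the chromosome. Numbered suffixes appear on 2680 IDs. These rows were kept as separate genes, 177 of them were tested, and none of those 177 changed. The number of IDs that matched any ID column of the RefSeq gene table for the Da-Ae assembly was 0, and the deposited table does not pair its IDs with gene names. For this reason no gene is named by function. The LEAFY copies and the gene lists of flowering, meristem, hormone, tissue-marker and stress genes that had been fixed before the data were examined are not analysed here.

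The library totals ran from 15922207 to 23261028 counts in genes. The floors used below cover counting error only. Reads without molecular identifiers are not independent molecules, so these floors may be too low. For a group with 0 counts in all its libraries, the fold was computed against a floor of 3 counts over the group. It is a lower bound on the side of that group only, since the other group was taken at its pooled level, without its spread.

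The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter at its default minimum count of 10 (48524 genes tested), group as the sole term and Benjamini-Hochberg adjustment. A gene was called changed at an adjusted p under 0.05. Standard errors of log2 fold changes were obtained from the F statistic. The common biological coefficient of variation, a single value shared by all genes, was 19.4%. A single set of counts was simulated for the same 48524 genes and this comparison. In it the test recovered 42 of 100 genes changed 2-fold and 86 of 100 changed 4-fold, all with the simulated sign. It made 17 false calls, 11.7% of all its calls, which is above the nominal rate. The simulated genes were drawn independently, with no library or chromosome segment set apart, so rates in the real data may differ.

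Per chromosome, changed genes were compared with the other placed genes by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over 19 chromosomes. Pairs of changed genes at most 5 ID numbers apart were compared with 10000 random draws of as many placed tested genes. This pair test was not among those fixed before the data were examined. Chromosome levels per library were computed from 39617 placed genes with a mean of at least 2 CPM, as log2(CPM + 0.5) minus the median of the other 5 libraries. Medians were taken per chromosome and over windows of 50 genes, and the break on C09 was placed by least squares. These level analyses were added after the data were seen.

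The rule for individual genes, fixed before the data were examined, was that without gene names only the 2 largest rises and 2 largest falls are given by ID. They had to be called changed, to have no overlap between the groups and to reach a mean of at least 1 CPM in the higher group. Alternatives were median-of-ratios or library-size scaling, no filter or a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom (limma 3.58.1), a replicate block, leaving out each library, a stricter adjusted p of 0.01, a fold threshold, and a test against a 1.2-fold change. Adjusted p-values that DESeq2 left undefined were kept so. The deviations of same-numbered libraries from their group means correlated at -0.13, -0.08 and 0.14. This gave no sign that the shared replicate numbers pair the libraries, but other pairings were not computed.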

Results

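LEAFY is a transcription factor that sets the identity of floral meristems. In rapeseed, an allotetraploid crop with an A and a C subgenome, the series asked what the second intron of the C3 copy contributes to inflorescence formation. It compared the shoot apex transcriptomes of the spring cultivar Westar and of intron 2 deletion mutants (below, the mutant). Each group had 3 libraries. The wild-type libraries 1, 2 and 3 held 23261028, 17797615 and 18255399 counts in genes, and the mutant libraries 18321109, 19017318 and 15922207.

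The apices expressed both subgenomes about equally. The A subgenome took 48.0% ± 0.168 of the counts in the wild type and 47.8% ± 0.329 in the mutant (SD, n = 3 each; exact two-sided permutation p = 0.6, where 0.1 is the smallest this design allows). The C subgenome took 50.04% ± 0.178 and 50.2% ± 0.313 (exact permutation p = 0.5, n = 3 each). The number of genes with at least 10 counts was 48549 ± 893 in the wild type and 48049 ± 402 in the mutant (SD, n = 3; exact permutation p = 0.5). The 10 most abundant genes of each library together took 2.93% to 4.31% of its counts. Log2 CPM values correlated across genes at 0.951 to 0.972 between libraries of a group and at 0.948 to 0.963 between groups. Counts of every pair differed by more than sampling noise, with a chi-square per gene of at least 8.11, so all 6 were counted as separate libraries. That lowest value was between groups, for wild-type library 2 and mutant library 1, and the lowest within a group was 9.16. These values do not show whether any libraries came from the same plant material. The first principal component (31.9% of the variance) separated the groups, with the wild-type libraries at -55.9 to -24.8. Mutant libraries 1 and 2 lay at 60.7 and 54 on it, but mutant library 3 lay between them and the wild type, at 10.9. The second component (25.01%) set mutant library 3 apart at -86.9, against -5.8 to 27.8 for the other 5 libraries.

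The mutant differed from the wild type at 94 of 48524 tested genes, 0.194% (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Of these, 60 rose and 34 fell. The genes that rose were low in the wild type, with a median of 1.54 CPM against 10.7 CPM in the mutant, and their median log2 fold change was 2.86. The genes that fell had a median of 7.86 CPM in the wild type and 1.97 CPM in the mutant, with a median log2 fold change of -1.94. Among the genes that rose, 57 changed by at least 2-fold and 28 by at least 8-fold. Among those that fell, 30 changed by at least 2-fold and 9 by at least 8-fold. The groups did not overlap at any of the 94 genes, which being called changed itself makes likely. They also did not overlap at 18.1% of all tested genes, where chance gives 10%, and 5587 genes (11.5%) had an unadjusted p under 0.05.

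The count changed when 1 library was left out. It was 18 without wild-type library 1, 56 without wild-type library 2, 26 without wild-type library 3, 32 without mutant library 1, 33 without mutant library 2 and 167 without mutant library 3. Fewer libraries can by themselves lower such a count, and this was not separated from an effect of the library left out. Only the count without mutant library 3 rose. With DESeq2 on all 6 libraries the count was 779, of which 505 rose, and those 779 held all 94.

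**Figure D1:**
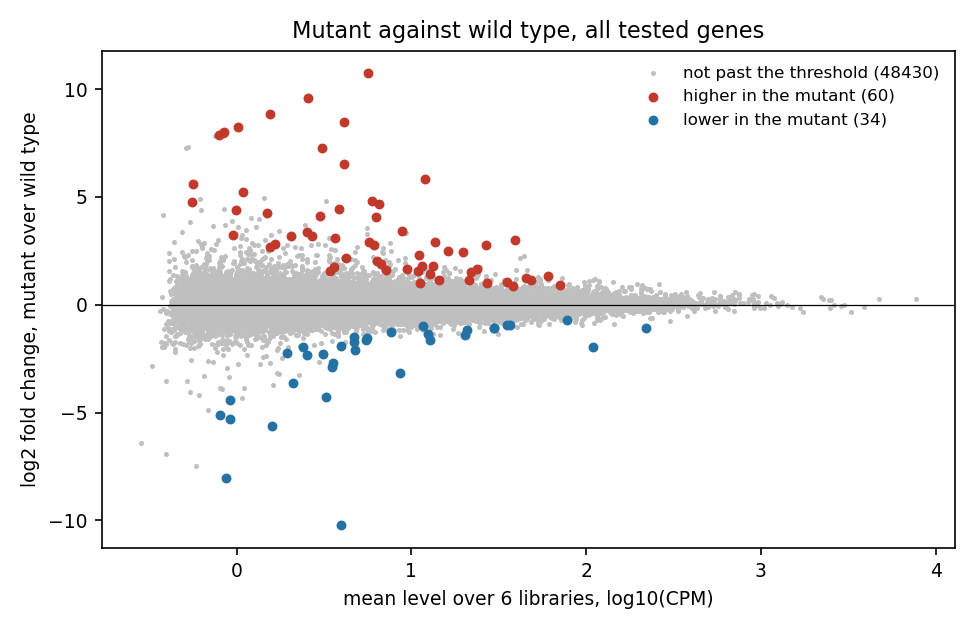
Log2 fold change of the mutant over the wild type (y axis) against the mean level over the 6 libraries in log10 CPM (x axis), 1 point per tested gene. The 60 genes that rose are red, the 34 that fell are blue, and the genes beyond 8-fold lie mostly at the low end of the level axis.

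A subset of the changed genes had reads in 1 group only. The wild type had 0 counts in all 3 libraries for 7 of the 60 genes that rose. These lay on 7 different chromosomes and had 17 to 313 counts per mutant library. The mutant had 0 counts in all 3 libraries for 2 of the 34 genes that fell. The 2 largest rises and the 2 largest falls were all of this kind. BnaA01T0221300WE, on chromosome A01, had 0 counts in each wild-type library and 60, 206 and 313 counts in the mutant libraries (11.3 ± 8.1 CPM, SD, n = 3). At the pooled mutant level this was at least 222-fold higher (edgeR adjusted p = 0.0353). Without mutant library 3, this lower bound was 147-fold. BnaC06T0099200WE, on C06, went from 0 counts to 83, 84 and 99 counts (5.13 ± 0.938 CPM, SD, n = 3), at least 102-fold higher (edgeR adjusted p = 0.00298).

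The 2 largest falls were neighbours on C04. BnaC04T0371400WE had 223, 129 and 134 counts in the wild-type libraries (7.95 ± 1.16 CPM, SD, n = 3) and 0 in every mutant library, at least 141-fold lower (edgeR adjusted p = 0.000943). BnaC04T0371600WE had 37, 29 and 38 counts (1.75 ± 0.257 CPM, SD, n = 3) and 0 in the mutant, at least 30.2-fold lower (edgeR adjusted p = 0.0238). The gene numbered between them had 0 counts in all 6 libraries. The genes on either side were expressed in both groups. The one before the pair (ID number 3713) had 644 counts over the wild-type libraries and 526 over the mutant libraries (log2 fold change -0.04, edgeR adjusted p = 0.973). The one after it (ID number 3717) had 9462 and 8526 counts (log2 fold change 0.03, edgeR adjusted p = 0.958). Further before the pair, ID number 3711 had 1623 and 781 counts, a lower level that did not pass (log2 fold change -0.81, edgeR adjusted p = 0.177). The calls of BnaC06T0099200WE and BnaC04T0371400WE held under all 14 alternatives run for them. That of BnaA01T0221300WE was lost in 6 of 14 (adjusted p up to 0.156) and that of BnaC04T0371600WE in 7 of 14 (adjusted p up to 0.111). No direction changed, but none could, since 1 group had 0 counts in every library.

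**Figure D2:**
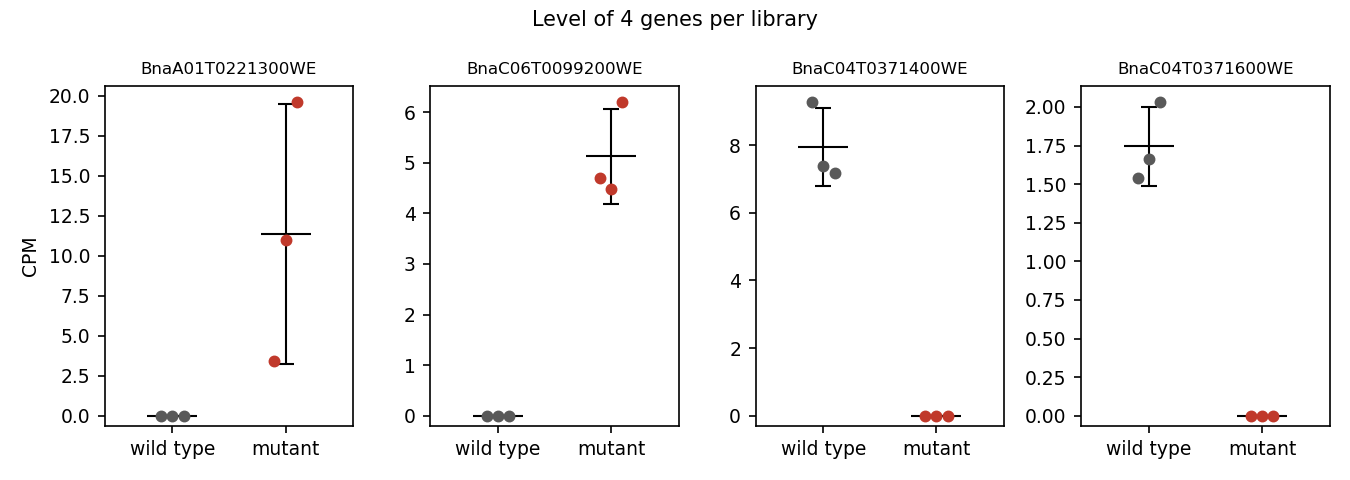
Level in CPM (y axis, linear) of the 2 genes with the largest rise and the 2 with the largest fall, by group (x axis). Points are single libraries, horizontal bars the mean and error bars the SD (n = 3), and in each panel 1 group is at 0 in all 3 libraries.

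Changed genes were spread over every chromosome. The A subgenome held 47 of them among 22434 tested (0.21%) and the C subgenome 46 among 25158 (0.183%; two-sided Fisher's exact test, p = 0.534, odds ratio 1.15). In the A subgenome 26 rose and 21 fell, and in the C subgenome 33 rose and 13 fell. This difference in direction did not pass a two-sided Fisher's exact test (p = 0.132). Chromosome C03, which carries the edited LEAFY copy, held 8 changed genes among 3751 tested, where an even spread gives 7.33, and 5 of the 8 rose (odds ratio 1.1, 95% interval 0.46 to 2.27). The number of chromosomes that departed from an even spread was 0 after adjustment, with 0 also at an unadjusted p under 0.05 (smallest Fisher's exact p = 0.288, for C09). Genes are not independent replicates, so these tests describe where the calls lie.

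**Figure D3:**
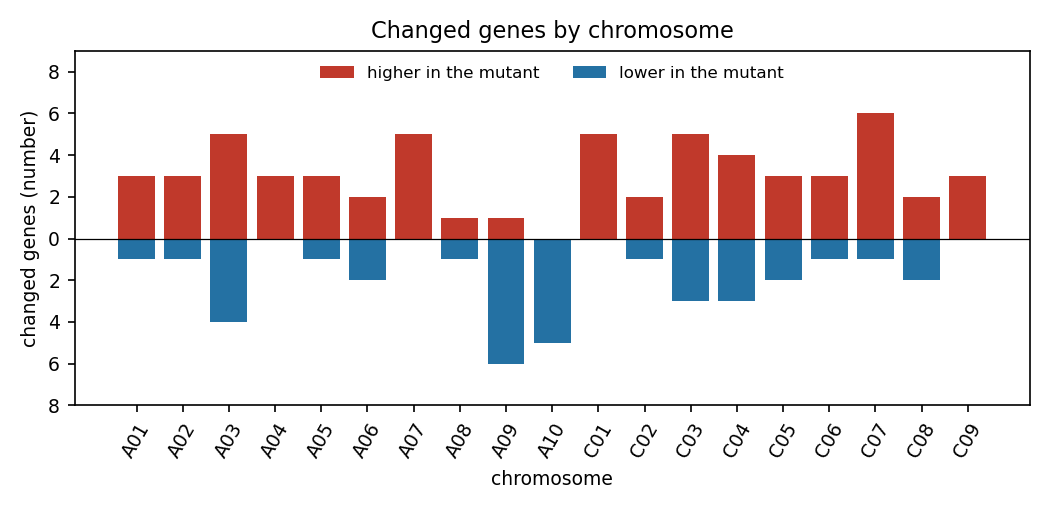
Number of changed genes (y axis) on each of the 19 chromosomes (x axis), with genes higher in the mutant drawn upward and genes lower in the mutant drawn downward. On A10 all 5 changed genes fell, and C03 held 5 that rose and 3 that fell.

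Some changed genes lay side by side. Among the 93 placed genes, 4 pairs were at most 5 ID numbers apart, on A03, C01, C04 and C08, where random draws gave a mean of 0.509 pairs (permutation p = 0.0021 over 10000 draws). This test was not planned, and the pair on C04 is that of the largest falls given above. The draws treat genes as independent, so nearby copies that share reads could also give such pairs. Both members rose on C01 and both fell on C04 and C08, while on A03 a gene that rose was next to one that fell.

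The calls on A10 and A09 were mostly falls, although neither passed a test. On A10 all 5 changed genes fell, and on A09 6 of 7 did. A test of falls alone, chosen after the data were seen, gave a Fisher's exact p of 0.00809 for A10 (adjusted p = 0.154) and 0.0274 for A09 (adjusted p = 0.26). On A10 the median log2 fold change over the 1774 tested genes was -0.102, against -0.011 to 0.026 for the other chromosomes. Mutant library 3 carried this shift in the median. Its A10 genes were at a median log2 deviation of -0.33 from the other 5 libraries (quartiles -0.55 and -0.11, 1505 genes), that is 79.3% of their level. The other 5 libraries lay at 0.035 to 0.05. The reference for each of those 5 included mutant library 3, which raises their values. Without mutant library 3, the A10 median log2 fold change was -0.002 and 2 of the 5 falls were still called, their 5-gene median moving from -1.34 to -1.25. Of the 8 genes then changed on A10, 5 rose and 3 fell. That fit called 167 genes in all, of which 120 rose. All 5 earlier falls stayed below 0 in it, with a highest log2 fold change of -1.12. The changed share therefore does not show that mutant library 3 made the lean to falls.

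A second library stood apart on another chromosome. In wild-type library 1 the first 882 genes of C09 (ID numbers 3 to 1960) lay at a median log2 deviation of -0.28 (quartiles -0.46 and -0.11). This is 82.4% of the level in the other libraries, which lay at 0.038 to 0.055. Their values are likewise raised by a reference that included wild-type library 1. The remaining 1654 genes of C09 in that library were at 0.011. Apart from A10 in all libraries and C09 in wild-type library 1, the 107 other chromosome medians ran from -0.027 to 0.028. With A10 left out of the fit, 87 genes changed (58 rose), and with A10 and C09 left out, 84 changed (55 rose). Without wild-type library 1 and mutant library 3 together, 51 genes changed, of which 44 rose and 7 fell, and 30 of the 51 were among the 94.

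**Figure D4:**
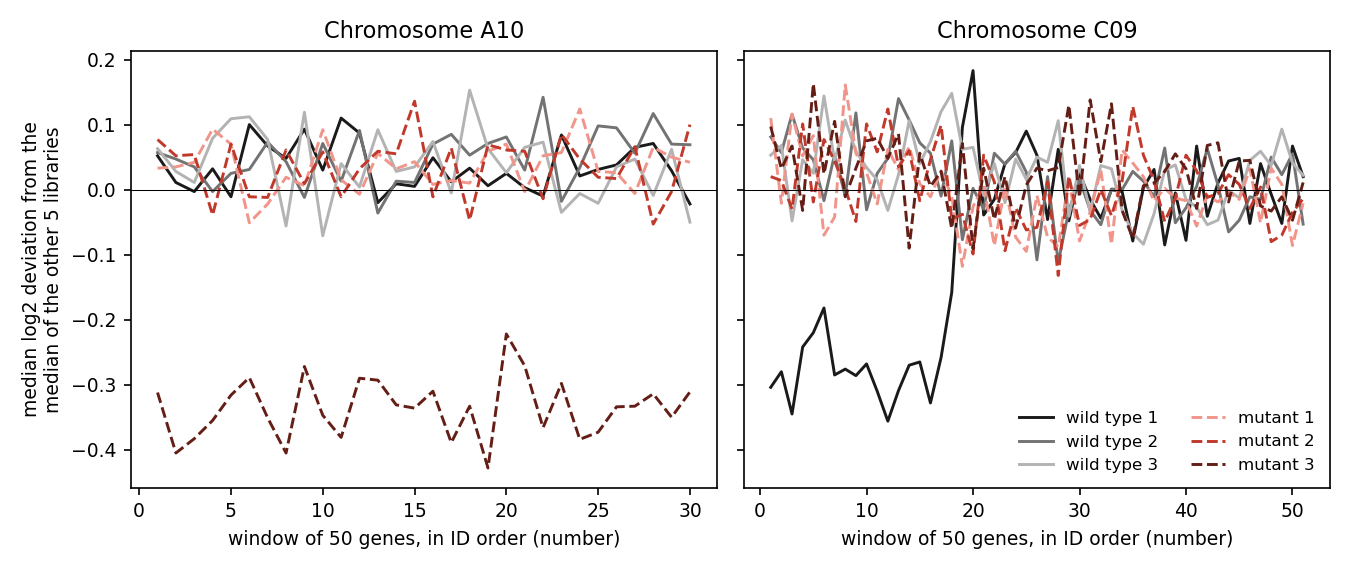
Median log2 deviation of each library from the median of the other 5 libraries (y axis) in successive windows of 50 genes along A10 and C09 in ID order (x axis), with wild-type libraries as solid and mutant libraries as dashed lines. Mutant library 3 lies between -0.428 and -0.222 in all 30 windows of A10, and wild-type library 1 lies between -0.356 and -0.182 in the first 17 windows of C09.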

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

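The 4 genes given by ID kept their direction in the 14 alternatives run for them. This was fixed in advance, since each had 0 counts in every library of 1 group. More genes rose than fell in each alternative of the gene count. The 94 changed genes became 451 (294 rose) with no filter beyond all-zero genes, 779 (505 rose) with DESeq2, 15 (12 rose) at an adjusted p under 0.01, and 51 (44 rose, 86.3%) without wild-type library 1 and mutant library 3, an alternative chosen after the data were seen. The 451 and the 779 each held all 94, and the cause of these differences was not tested, nor was that of the 51, which has fewer libraries and lacks those that stand apart. Leaving out 1 library, which also leaves fewer to test, gave 18 (without wild-type library 1) to 167 (without mutant library 3), with 18 to 72 of the 94 among them. With the replicate number as a block the count was 49 (35 rose), 40 of them among the 94. The correlations of -0.13, -0.08 and 0.14 gave no sign that the numbers pair the libraries. They cannot exclude it, since other pairings were not computed. Whether the block removes a real batch or only costs power is therefore open. The other alternatives gave 67 to 113 genes. TMM, median-of-ratios and library-size scaling called 94, 98 and 113 genes, of which 63.8%, 65.3% and 61.9% rose. The number of chromosomes departing from an even spread stayed at 0 in all 8 alternatives run for it. The LEAFY copies and the fixed gene lists gave no value, since the IDs were not paired with names. Of the 10 splits of the 6 libraries into 3 and 3, only the real one (1 of 10) reached 94 calls, and the highest other split gave 32. With 10 splits no share can fall under 0.05. In the single set of counts simulated for this comparison at these depths, with 3 libraries per group, 42% of 2-fold and 86% of 4-fold changes were recovered. What depth alone limits was not tested.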

Other observations

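The full table, tested or not, held 16 genes with 0 counts in all 3 libraries of 1 group and at least 10 counts in each library of the other. The wild type lacked reads for 10 of them and the mutant for 6. They lay on 10 chromosomes, and 9 of the 16 were among the 94 changed genes. The other 7 had 10 to 41 counts per library in the group with reads. Outside A10 and C09, mutant library 3 also scattered more widely than the rest: its median absolute log2 deviation was 0.217, against 0.166 to 0.173 in the other 5 libraries. The tests of where the genes with reads in 1 group lie, of few genes and gained segments on A10, of lower dose on A10 and C09, and of the splits for the 94 calls were chosen after the result was seen. The matched lists, the gained segments for C09 and the splits for the genes with reads in 1 group were chosen before theirs.

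The A10 shift in mutant library 3 covered the chromosome. A library-wide effect of scaling or expression level is argued against by the other chromosomes, whose medians were near 0. The lowest median of 10000 expression-matched lists from them was -0.024. Those chromosome medians bound the lists to lie near 0, so the lists add little. Medians in 30 of 30 windows lay below -0.1. This restates the low A10 median, which a few strongly changed genes could not give. An added segment elsewhere in place of A10 is argued against by 0 windows at or above 0.2 and 7 at or above 0.15 on the other chromosomes, against the 30 that fell. Outside A10 and C09, 1 window was as low in this library (-0.285), the last 22 of the A09 genes used for levels. A lower dose of A10 in part of the tissue and a coordinated fall in its transcription cannot be told apart: the library was the lowest of 6 in 30 of 30 A10 windows, which the choice of the pattern fixes and both predict, and DNA was not measured. GC content was not tested, and the design names no group that separates this library.

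The first part of C09 in wild-type library 1 showed the same form with a break inside the chromosome. Expression-matched lists reached no lower than -0.037, but the other chromosome medians bound them to lie near 0. Elsewhere, 3 windows were at or above 0.15 and 0 at or above 0.2. The highest of the 3, at 0.183, lay on C09 itself, past the break. An added segment of equal size would need about as many as the 17 that fell. A lower dose of this segment in part of the tissue stays open beside a coordinated fall in transcription. The library was the lowest of 6 in 17 of 17 windows, but the segment was drawn from these low values, so this decides nothing. GC content was not tested here either. Each shift was seen in 1 library and not in the others of its group, A10 in a mutant and C09 in a wild-type library. With 1 library each, a link to the genotype can be neither shown nor excluded. Whether the plants of each library were pooled is not stated.

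The 16 genes with reads in 1 group may reflect sequence or expression differences between the lines in addition to the edit, which is a hypothesis. Sampling of low counts is argued against, because the highest of the 9 other splits of the libraries gave 1 such gene. Linkage to the edited locus is argued against as their common origin, because 0 of the 16 lay on C03. On C04 the silent pair was bounded by expressed genes on both sides, which a small deletion or a local loss of expression would give. Reads shared between near-identical copies, and effects of the deletion on genes elsewhere, stay open, as no sequence was used and the labels name no second line.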
